A study of Mus musculus with 2 samples.

How the data were processed

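Kidney sections from mice with unilateral ureteral obstruction, a surgical model in which the ureter of 1 kidney is tied off, were profiled by spatial transcriptomics on 10x Genomics Visium slides, on which barcoded spots capture the polyadenylated RNA of the tissue above them. Per the labels' protocols, fresh frozen kidneys were embedded in OCT and cut at 10 µm. A spot covers a small area that can hold several cells of different types. The wider study, per its design text, used 6 mice and harvested kidneys 7 days after surgery. It profiled 9 kidneys by single-cell sequencing, 3 per group including contralateral control kidneys, and 2 of the kidneys also by spatial transcriptomics. Those 2 sections are analysed here: 1 from a mouse given SH045 and 1 from a mouse given vehicle. The single-cell data are not analysed here.

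For each section the authors deposited a matrix of UMI counts (counts of distinct captured RNA molecules) per gene and spot, which is not normalized, with the spot barcodes, the gene identifiers and symbols, and a table of spot positions. Per the file headers the matrices came from Space Ranger version 2.0.1, and per the submitters' processing notes the genome build was mm10. Alignment settings and the gene annotation release are not given in the sources used here. Both matrices list the same 32285 genes. The matrices hold 790 spots for the SH045 section and 676 for the Vehicle section, out of 4992 on a slide area. In the SH045 positions table the tissue flag marks exactly the 790 spots of the matrix. In the Vehicle positions table it marks 1210 spots, of which 570 are among the 676 in the matrix, so the flag and the matrix do not belong to the same tissue outline. Every spot in the Vehicle matrix was therefore used, grid positions were taken from the table, and the flagged spots alone were tried as an alternative. Image files and scale factors were not used here.

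Sections were assigned to groups from the treatment given in the labels. With 1 section per group, from 1 mouse each, no test between groups was possible, spots were not treated as replicates, and no p-value is given. UMI counts were summed over the spots of a section and expressed as CPM, that is, scaled to a total of 1000000 UMIs over all genes. Each CPM has an exact Poisson 95% interval, each fold an exact conditional binomial 95% interval and each share of spots an exact (Clopper-Pearson) 95% binomial interval. These intervals cover counting error only, and neither the variation between mice nor that between sections. The log2 ratio of a gene is the difference of log2(CPM + 1) between the SH045 and the Vehicle section. A pseudocount of 1 CPM understates the ratio of genes of low level. Folds against a section with no UMI were computed against a floor of 3 counts in that section, which equals 0.134 CPM in the SH045 section and 0.693 CPM in the Vehicle section, and are given as lower bounds. Each section was also split into 4 blocks of similar spot number by position, and the range of CPM over these blocks describes the spread within a section.

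Before the data were examined, 47 gene lists were fixed, 23 of them cell type markers. A member was measured if it reached 10 CPM in at least 1 section, and was called higher or lower at 1.5-fold or more. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these 2 libraries. Genes are named by a rule also fixed beforehand: the TRPC channel genes, the 12 genes of highest and 12 of lowest log2 ratio among genes with at least 50 CPM in the higher section whose ranges over the blocks do not overlap between sections and whose direction holds under every scaling, the 3 members of highest level of each list, and the 5 genes of highest fold over the rest of the section in each region, among genes with at least 50 CPM in the region. Mitochondrially encoded, ribosomal protein, haemoglobin and immunoglobulin genes and predicted gene names were left out of the highest and lowest genes. Any gene named outside this rule is said to be so. Gene positions were taken from the RefSeq annotation of the mm10 assembly by symbol, with 150 of 153 named genes matched.

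Regions were found in each section on its own with scanpy 1.11.5: log-normalised counts, 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.6. They are described by their leading genes, and region shares are not compared between sections. No doublet caller was run, because a spot is not a cell. For shares of spots with a UMI and for correlations of list scores across spots, each spot was thinned at random to 2500 UMIs, which left out 2 SH045 and 115 Vehicle spots. A list score is the mean over members of the log of 1 plus the thinned count, and genes shared by both lists of a pair were left out of both. Distance from the tissue edge was counted in grid steps.

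The interval and list calculations were tested on data simulated from the gene levels pooled over the 2 sections and the depth of each, with 200 genes changed by known folds. The fold intervals covered the true value for 95.25% of 3810 genes, and 95.67% of 300 unchanged random lists fell inside the central range. Simulated counts were Poisson, which the intervals assume, so this checks the calculation and not whether that assumption holds for the sections. Alternatives fixed beforehand covered scaling (edgeR 4.0.16 TMM and median-of-ratios factors, totals without mitochondrially encoded, ribosomal or haemoglobin genes), weighting of spots, minimum UMIs, distance from the edge, thinning to the same median of UMIs per spot, pseudocount, expression filter, the summary of a list, clustering settings, thinning and the kind of correlation. A further 3 choices of spots were added after seeing the data: Vehicle spots with under 10% mitochondrially encoded counts, Vehicle spots with the tissue flag, and the largest connected block of spots in each section. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.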

Results

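Kidney sections from 2 mice with unilateral ureteral obstruction were compared at day 7 after surgery, 1 given SH045 and 1 given vehicle. SH045 is larixyl N-methylcarbamate, an inhibitor of the calcium-permeable cation channel TRPC6, and the comparison asks how gene expression in the obstructed kidney differs under the inhibitor. The SH045 section held 22388623 UMIs in 790 spots, with a median of 27733 UMIs per spot (range 392 to 72340) and a median of 6978.5 genes per spot. The section labelled Vehicle held 4327613 UMIs in 676 spots, with a median of 4932.5 UMIs (range 122 to 33673) and 2058.5 genes per spot, so the median spot was 5.62 times deeper in the SH045 section. At least 1 UMI was found for 19079 genes in the SH045 section and for 15661 genes in the Vehicle section. The 20 most abundant genes took 11.9% of the UMIs in the SH045 section and 23.5% in the Vehicle section, and mitochondrially encoded genes took 4.24% and 10.4%. Over the 10463 genes with at least 10 CPM in either section, the median log2 ratio was 0.63 in favour of the SH045 section and 75.7% of genes lay above 0. This shift was 0.07 with TMM factors and 0.03 with median-of-ratios factors over the same genes, so a list median given below without its value relative to all genes includes this shift of 0.63. Counts of higher and lower genes are at 1.5-fold without regard to the shift, unless said to be relative to all genes.

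Genes of injured or dedifferentiated tubule stood at higher levels in the SH045 section, summing to 29643 CPM against 1849 CPM in the section labelled Vehicle, where Havcr1 and Lcn2 were near the detection limit. Havcr1, which encodes the kidney injury molecule KIM-1 (ENSMUSG00000040405, chromosome 11, 46739822 to 46779578), was at 992 CPM (95% interval 979 to 1006) in the SH045 section and at 1.62 CPM (0.65 to 3.33, from 7 UMIs) in the Vehicle section, a fold of 614 (298 to 1526). Lcn2, encoding the iron-binding injury marker lipocalin 2 (ENSMUSG00000026822, chromosome 2, 32384637 to 32387739), was at 1233 against 2.08 CPM, a fold of 593 (312 to 1296). Over the 4 position blocks of a section, Havcr1 ranged from 477 to 1319 CPM in the SH045 section and from 0 to 4.40 CPM in the Vehicle section. All 20 measured genes of the injured or dedifferentiated tubule list were higher in the SH045 section by at least 1.5-fold. Their median log2 ratio was 3.81, which is 3.17 above that of all genes and above all 10000 random lists, and relative to all genes 19 of the 20 were higher. Spp1, encoding osteopontin, reached 17076 CPM against 754 CPM, and Clu, encoding the chaperone clusterin, 6386 against 630 CPM. With every spot thinned to 2500 UMIs, Havcr1 was seen in 73.4% of 788 SH045 spots (70.1 to 76.4%) and in 0.535% of 561 Vehicle spots (0.110 to 1.55%), while the proximal tubule phosphate transporter Slc34a1 was seen in 52.0% and 98.6%. Without thinning the Havcr1 share in the SH045 section was 99.1%.

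**Figure D1:**
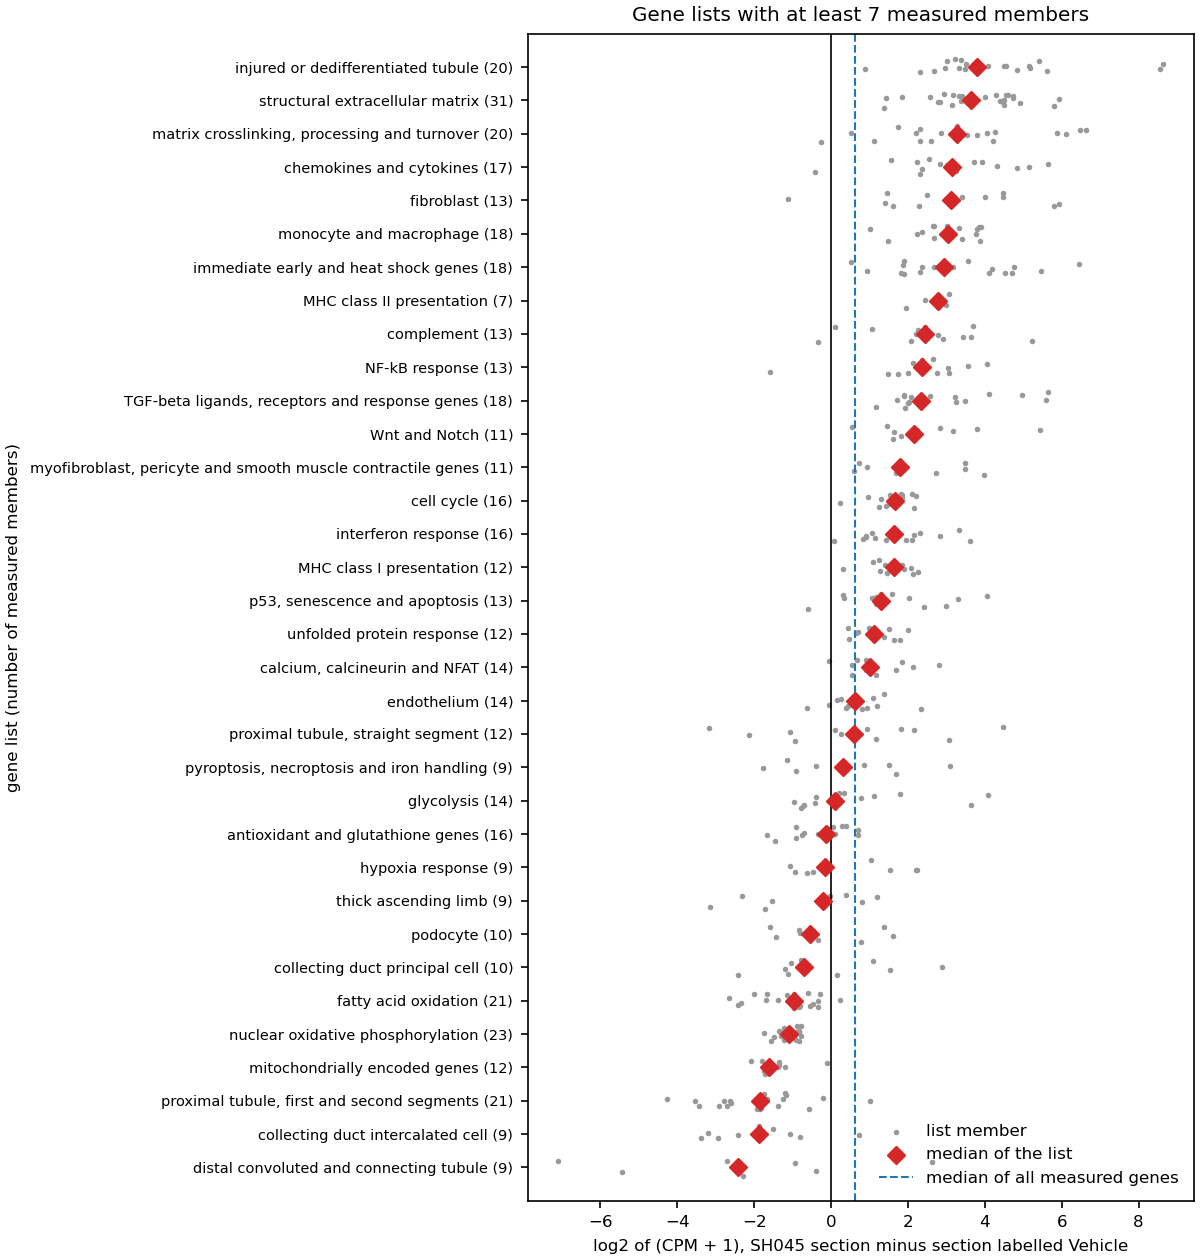
Log2 ratio of (CPM + 1), SH045 section minus the section labelled Vehicle, on the x axis for the measured members (grey points) and the median (red diamonds) of 34 gene lists with at least 7 measured members, 1 section per group and no replicate error. The injured tubule and structural matrix lists have medians of 3.81 and 3.65, the distal convoluted and connecting tubule list a median of -2.41, and the dashed line marks the median of all measured genes at 0.63.

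Structural extracellular matrix genes formed another group that was higher in the SH045 section in full. Each of the 31 measured structural matrix genes was at least 1.5-fold higher there, with a median log2 ratio of 3.65, or 3.01 above all genes, and relative to all genes the count was also 31. The list summed to 14823 against 2426 CPM. The fibrillar collagen genes Col1a1 and Col3a1 stood at 623 and 1013 CPM in the SH045 section and at 9.24 and 17.3 CPM in the Vehicle section, folds of 67.4 (49.5 to 94.3) and 58.4 (46.6 to 74.3). Sparc, a collagen-binding matrix protein gene, stood at 1292 against 123 CPM. Of 20 measured genes for matrix crosslinking and turnover 18 were higher and none lower, and they summed to 4000 against 1475 CPM. Among these were Timp1, an inhibitor of matrix metalloproteinases, at 235 against 1.39 CPM (a fold of 169, 77.8 to 462), and Mmp7, a matrix metalloproteinase, at 100.5 against 0.462 CPM. Timp3 was within 1.5-fold, at 636 against 765 CPM. Fibroblast markers had a median of 3.13, with 12 of 13 higher and 1 lower, and contractile genes a median of 1.79, with 10 of 11 higher (8 relative to all genes), such as Acta2, encoding smooth muscle actin, at 406 against 35.6 CPM. All 18 measured TGF-beta ligand, receptor and response genes were higher, with a median of 2.35. Ccn1 and Ccn2, matricellular response genes, stood at 457 and 670 CPM against 13.6 and 37.7 CPM.

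Immune genes were higher in the SH045 section as well. All 18 measured monocyte and macrophage markers were higher, with a median log2 ratio of 3.04, or 2.41 above all genes, and 17 were higher relative to all genes. Apoe, Lyz2 and the complement gene C1qb stood at 2166, 601 and 457 CPM against 145, 39.7 and 70.7 CPM. Of 17 measured chemokine and cytokine genes 16 were higher (median 3.16), including Cx3cl1 at 362 against 39.7 CPM, and Mif was within 1.5-fold. By summed level, 1883 against 745 CPM, the log2 ratio of that list was 1.34. All 7 measured MHC class II genes (median 2.79), 11 of 12 MHC class I genes (1.63), 11 of 13 complement genes (2.44) and 15 of 16 interferon response genes (1.63) were higher, with none lower in these lists. Relative to all genes the higher genes numbered 7, 10, 10 and 10, with 1 complement gene lower. Complement C3 reached 885 CPM against 22.9 CPM, a fold of 38.7 (31.8 to 47.6), and the MHC class II chaperone gene Cd74 1829 against 230 CPM. In the NF-kB list 12 of 13 genes were higher (median 2.38) and Sod2, which encodes mitochondrial superoxide dismutase, was lower at 169 against 506 CPM. By summed level, 1034 against 667 CPM, that list lay at the shift of all genes (log2 ratio 0.63). All 4 measured B and plasma cell genes were higher (median 2.81), such as Igkc at 1126 against 90.6 CPM. No T or NK cell gene reached 10 CPM. Summed over the 15 genes of that list, the level was 56.6 CPM (53.5 to 59.8) in the SH045 section and 10.4 CPM (7.58 to 13.9) in the Vehicle section. The only measured neutrophil gene, S100a9, stood at 9.74 and 10.6 CPM with overlapping intervals. Summed over the 11 genes of the neutrophil list, the level was 33.2 CPM (30.9 to 35.7) in the SH045 section and 21.3 CPM (17.1 to 26.1) in the Vehicle section. Of 3 measured dendritic cell genes 2 were higher and Batf3 was at 10.2 and 10.6 CPM.

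The following stress, growth and signalling lists had medians above the all-gene shift too, while the hypoxia response and antioxidant lists, given further below, did not. Of 18 immediate early and heat shock genes 17 were higher, with a median of 2.93, and Egr1, an early growth response transcription factor gene, stood at 168 against 0.924 CPM. Of 16 cell cycle genes 15 were higher (median 1.66), of 11 Wnt and Notch genes 10 (2.15), of 13 p53, senescence and apoptosis genes 10 (1.29, with 1 lower), and of 12 unfolded protein response genes 10 (1.11). Relative to all genes 14 cell cycle, 10 Wnt and Notch, 7 p53 and 5 unfolded protein response genes were higher. Gdf15, a stress-induced cytokine gene of the p53 list, stood at 270 against 15.3 CPM. Of 14 calcium, calcineurin and NFAT genes 11 were higher (4 relative to all genes), with a median 0.37 above that of all genes and at percentile 85.1 of random lists. Among the genes of highest ratio, Aoc1, which encodes the polyamine-degrading diamine oxidase, stood at 358 against 0.924 CPM, and Smoc2, a matricellular protein gene, at 156 against 1.16 CPM. Sprr1a, a cornified envelope gene, stood at 129 against 0.462 CPM. Serpina10, Lgi2 and the urea transporter gene Slc14a2 had 2510, 1980 and 1850 UMIs in the SH045 section and none in the Vehicle section, so against the floor of 3 counts they were at least 161.7-fold, 127.5-fold and 119-fold higher, and the exact 95% intervals of the folds start at 131.4, 103.6 and 96.8.

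Transporter and metabolic genes of healthy tubules lay on the other side, at higher levels in the section labelled Vehicle. Of 21 genes of the first and second proximal tubule segments 18 were lower in the SH045 section and 1 was higher, with a median log2 ratio of -1.84, or -2.48 relative to all genes. Slc34a1 stood at 585 CPM in the SH045 section and 4413 CPM in the Vehicle section, and Miox, encoding myo-inositol oxygenase, at 221 against 2577 CPM. Distal convoluted and connecting tubule genes had a median of -2.41, with 7 of 9 lower and 1 higher. Pvalb, encoding parvalbumin, had 3 UMIs in the SH045 section and 669 in the Vehicle section, 1154-fold higher in the latter (393 to 5608). Calb1, encoding calbindin, stood at 29.3 against 1311 CPM. The collecting duct intercalated cell list had a median of -1.88 (8 of 9 lower), and the principal cell list one of -0.70 (6 of 10 lower, 3 higher). Klk1, encoding the tubular serine protease kallikrein 1 (ENSMUSG00000063903, chromosome 7, 44225360 to 44229622), stood at 163 CPM against 11178 CPM, 68.7-fold higher in the Vehicle section (66.4 to 71.0). S100g, encoding a calcium-binding protein of the distal nephron, was 59.7-fold higher there (57.7 to 61.8). The other genes of lowest ratio were Cyp2d12, Slc22a8, Ces1e, Acmsd, Inmt, Fam151a, Atp4a and Nat8f1, all between 12.4-fold and 27.7-fold higher in the Vehicle section. Thin limb genes were an exception among the tubule lists, with a median of 2.01, or 1.38 above all genes, and 4 of 6 higher and none lower in the SH045 section (1 lower relative to all genes). By summed level, 823 against 504 CPM, their log2 ratio was 0.71, close to the shift of all genes.

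Genes of oxidative phosphorylation and fatty acid oxidation were also mostly lower in the SH045 section, while glycolysis genes, given below, had members on both sides. All 23 nuclear oxidative phosphorylation genes were lower, with a median of -1.09, and Atp5b, encoding the ATP synthase beta subunit, stood at 1486 against 2983 CPM. Of 21 fatty acid oxidation genes 15 were lower and none higher (median -0.95). Mitochondrially encoded genes had a median of -1.60, with 11 of 12 lower. All genes of the list summed to 203910 and 177975 CPM in Vehicle regions 1 and 4, but to 32414, 36241 and 30147 CPM in Vehicle regions 2, 3 and 5. In the SH045 section they summed to 42436 CPM, with regions from 24657 to 72474 CPM. Vehicle regions 2, 3 and 5 thus lay within the range of the SH045 regions. Spots were also chosen after seeing the data, as the 334 Vehicle spots with under 10% mitochondrially encoded counts. Against these alone the median of the mitochondrially encoded genes was 0.42, a value that choosing spots by the same counts makes higher by construction. In that comparison the nuclear oxidative phosphorylation genes had a median of -1.10 with 23 of 23 lower, the injured tubule list had a median of 3.72 (20 of 20 higher), the structural matrix list 3.53 (31 of 31), the macrophage list 2.93 (18 of 18) and the first proximal list -1.92 (17 of 20 lower).

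**Figure D2:**
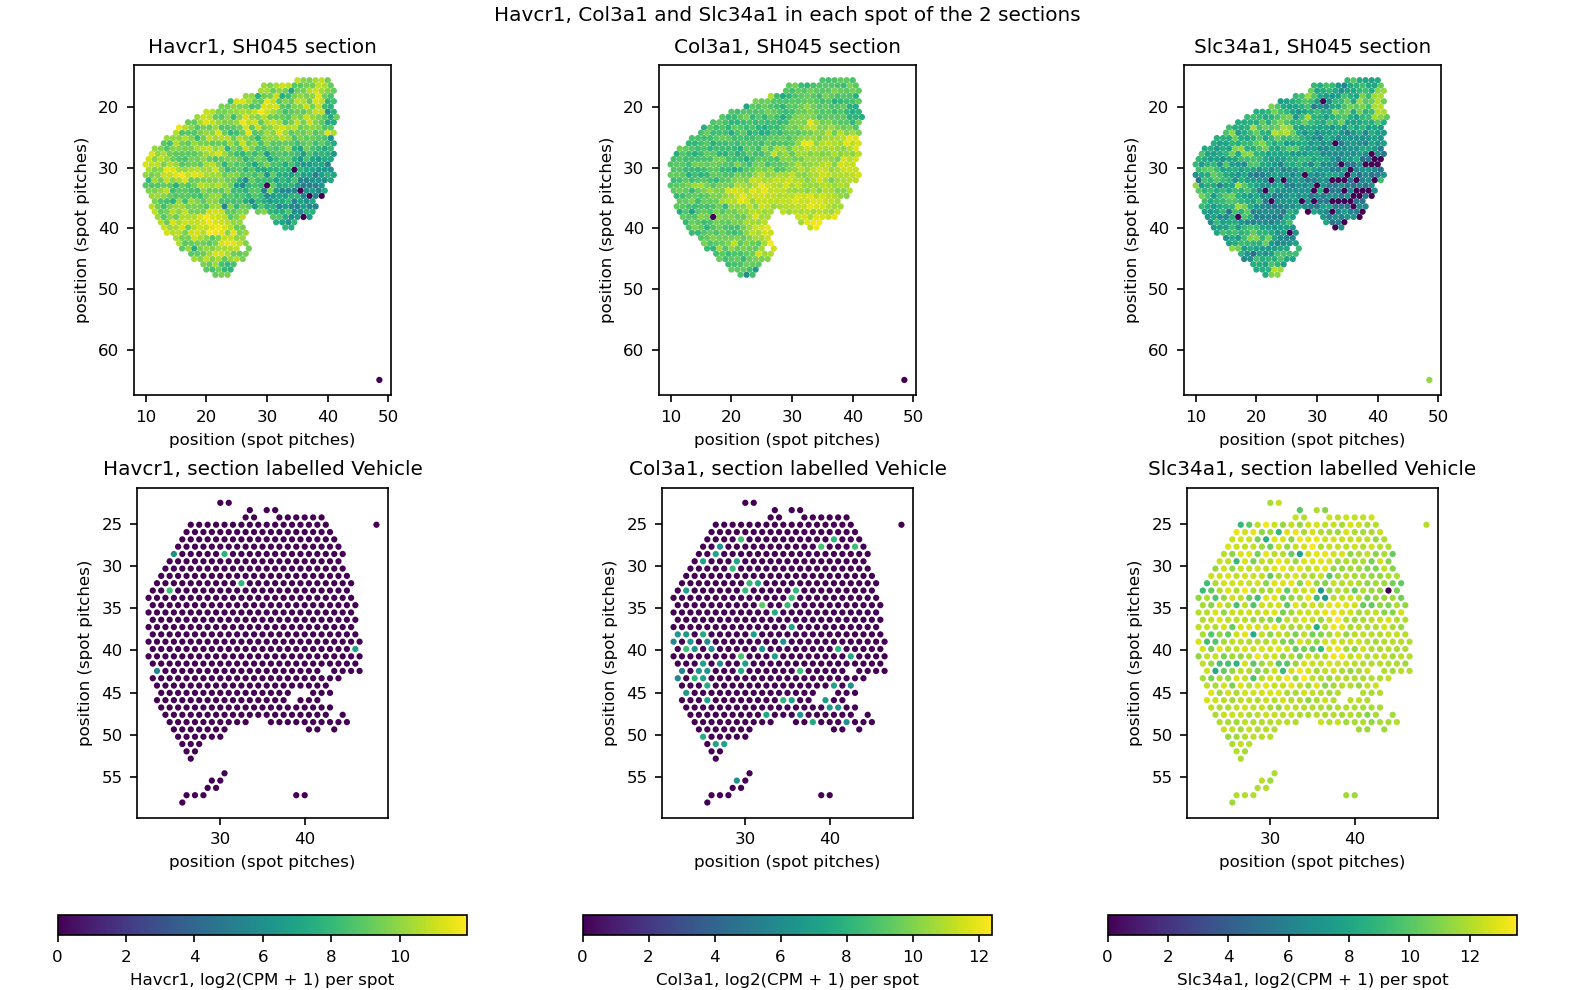
Havcr1, Col3a1 and Slc34a1 in each spot, as log2(CPM + 1) by colour, in the SH045 section (top) and the section labelled Vehicle (bottom), with axes in spot pitches. Over whole sections Havcr1 stood at 992 and 1.62 CPM, Col3a1 at 1013 and 17.3 CPM and Slc34a1 at 585 and 4413 CPM.

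Other lists had members on both sides, medians near that of all genes, or few measured genes. The proximal straight segment list had a median of 0.60 with 6 genes higher and 4 lower of 12, but its summed level was lower in the SH045 section (1627 against 4299 CPM), and the sign of its median turned under other settings. Cyp4b1 of that list stood at 218 against 1988 CPM and Atp11a at 519 against 272 CPM. The endothelium list had a median of 0.62, equal to the shift of all genes within 0.01. The thick ascending limb list had a median of -0.20, while its summed level was higher in the SH045 section because Umod, encoding uromodulin, stood at 3373 against 1470 CPM. Podocyte genes had a median of -0.54, with 5 of 10 lower and 3 higher. Glycolysis (0.10), hypoxia response (-0.17), antioxidant and glutathione (-0.14) and the list of pyroptosis, necroptosis and iron handling genes (0.30) had medians below that of all genes, with members on both sides. Their summed levels were all lower in the SH045 section: 5644 against 8263 CPM for glycolysis, 2022 against 3178 CPM for hypoxia response, 15381 against 38731 CPM for antioxidant and glutathione, and 9317 against 17575 CPM for the last list. Nuclear-retained RNAs had a median of 0.50, with 1 of 3 higher. Lists with 1 to 3 measured genes were urothelium (2 of 2 higher), lymphatic endothelium (3 of 3), erythroid cells (3 of 3), perirenal fat (Fabp4 at 155 against 35.1 CPM) and renin cells (Ren1 at 175 against 99.6 CPM). Relative to all genes 2 lymphatic, 1 erythroid and 0 renin cell genes were higher. No adrenal gene was measured.

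TRPC channel transcripts were rare in both sections. Trpc6 (ENSMUSG00000031997, chromosome 9, 8543867 to 8680752) had 38 UMIs in the SH045 section, or 1.70 CPM (1.20 to 2.33), and 1 UMI in the Vehicle section, or 0.231 CPM (0.00585 to 1.29). The fold of 7.35 had an interval from 1.24 to 298, and the ranges over position blocks overlapped. After thinning, Trpc6 was seen in 2 of 788 SH045 spots and in 1 of 561 Vehicle spots. Trpc1 was the most abundant member, at 17.2 CPM (15.5 to 19.0) in the SH045 section and 22.9 CPM (18.6 to 27.9) in the Vehicle section. Trpc4 had 4 and 3 UMIs. No UMI of Trpc5 or Trpc7 was seen, for which the 95% upper limits are 0.165 CPM in the SH045 section and 0.852 CPM in the Vehicle section.

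The SH045 section divided into 8 regions. Region 1 (167 spots) held the renin gene Ren1 among its leading genes, at 538 CPM against 72.7 CPM in the rest of the section. Region 2 (170 spots) was led by Ccl5, the adhesion molecule gene Vcam1 (558 against 179 CPM) and the monocyte chemokine gene Ccl2 (114 against 39.8 CPM), and had the highest MHC class II level, 6291 CPM summed. The median spot of regions 1 and 2 lay 3 steps from the edge, and that of regions 4, 6 and 8 at 7, 7 and 8 steps. Region 3 (98 spots) was led by Igfbp2 and the thyroid hormone deiodinase gene Dio2 (286 against 27.2 CPM). Region 4 (67 spots) was led by Fst, encoding follistatin, and held Slc12a1, the cotransporter gene of the thick ascending limb, at 983 against 167 CPM. Region 5 (78 spots) was led by Krt14 and Ivl, genes of stratified epithelium, and by the matrix gene Col6a4. Its structural matrix level was the highest of the 8, 27967 CPM summed. Region 6 (95 spots) was led by the immunoglobulin gene Ighg2c. Region 7 (59 spots) was led by Slc22a8, Acmsd and Miox, and its first and second segment list, 15262 CPM summed, was the highest. Its injured tubule and matrix levels were the lowest of the section, at 14583 and 8572 CPM summed. Region 8 (56 spots) was led by Serpina1d, Slc22a7 and Slc22a19 and had the highest straight segment level, 4882 CPM.

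The section labelled Vehicle divided into 5 regions. Regions 1 and 4 (221 and 120 spots) had mitochondrially encoded genes among their leading genes, which took 20.4% and 17.8% of their UMIs, with Gm42418 and Lars2 also among the 10 leading genes of both. Gm42418 stood at 6989 and 6516 CPM there, against 2368 and 2157 CPM in the rest of the section. Region 2 (135 spots) was led by Nupr1, Ccl21a and the podocyte transcription factor gene Wt1 (53.05 against 6.44 CPM). Region 3 (157 spots) was led by Pllp and Ggct and had the highest levels of the first and second segment list, 27740 CPM summed. Region 5 (43 spots) was led by Klk1 at 73344 against 6649 CPM. The summed injured tubule level ran from 907 CPM in region 3 to 5761 CPM in region 5. The lowest region of the SH045 section, region 7, was 2.53-fold above the highest of the Vehicle section. Havcr1 had at most 5 UMIs in any Vehicle region and stood between 140 and 1636 CPM in the SH045 regions.

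**Figure D3:**
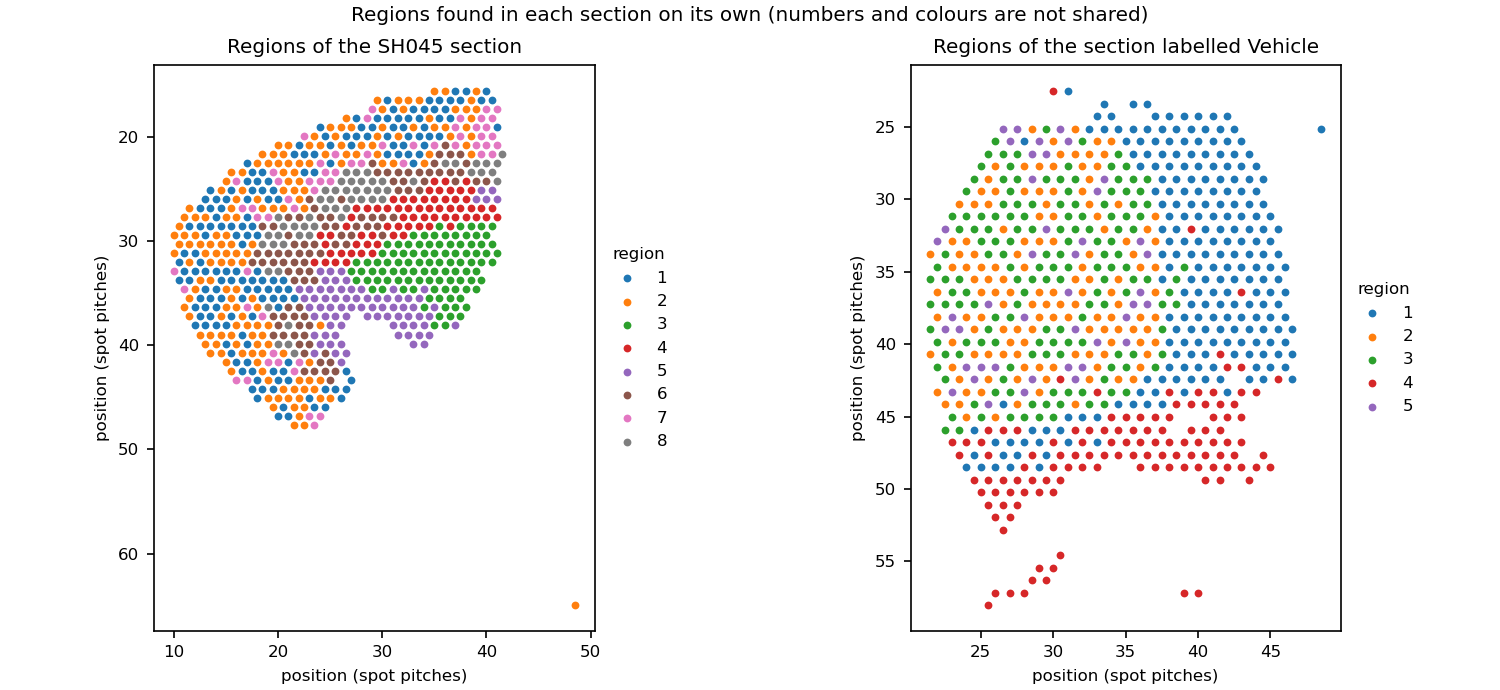
Regions of the SH045 section (left, 8 regions) and of the section labelled Vehicle (right, 5 regions), each found on its own, with axes in spot pitches and 1 point per spot. Region numbers and colours are not shared between the sections, which hold 790 and 676 spots.

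Within each section, gene lists were set against each other across spots thinned to 2500 UMIs. Spots are not independent, so these correlations are descriptions of 1 section each. Over the 788 SH045 spots, structural matrix genes correlated negatively with the genes of the first and second proximal segments (Pearson r = -0.63) and positively with contractile genes (0.51), TGF-beta response genes (0.51) and endothelium (0.36). The correlation of matrix genes was weaker with macrophage markers (0.22) and injured tubule genes (0.22). Proximal and injured tubule genes correlated at -0.51. Over the 561 Vehicle spots the matching values were -0.40, 0.42, 0.31, 0.44, 0.31, 0.34 and -0.61, with the same signs. T and NK cell genes showed r of 0.07 with matrix genes in the SH045 section and 0.04 in the Vehicle section. By distance from the edge, structural matrix genes summed to 15677 CPM in the outer 1 to 2 steps and 14282 CPM at 6 or more steps in the SH045 section, and to 2334 and 2503 CPM in the Vehicle section. Thick ascending limb genes summed to 2838 and 6645 CPM in the same bands of the SH045 section.

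With 1 section per group no difference above has a replicate check, and section, mouse, depth and treatment move together. The positions table of the Vehicle section flags 570 of its 676 matrix spots as tissue, and 342 of the 676 spots carried at least 10% mitochondrially encoded counts, against 20 of 790 in the SH045 section.

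**Figure D4:**
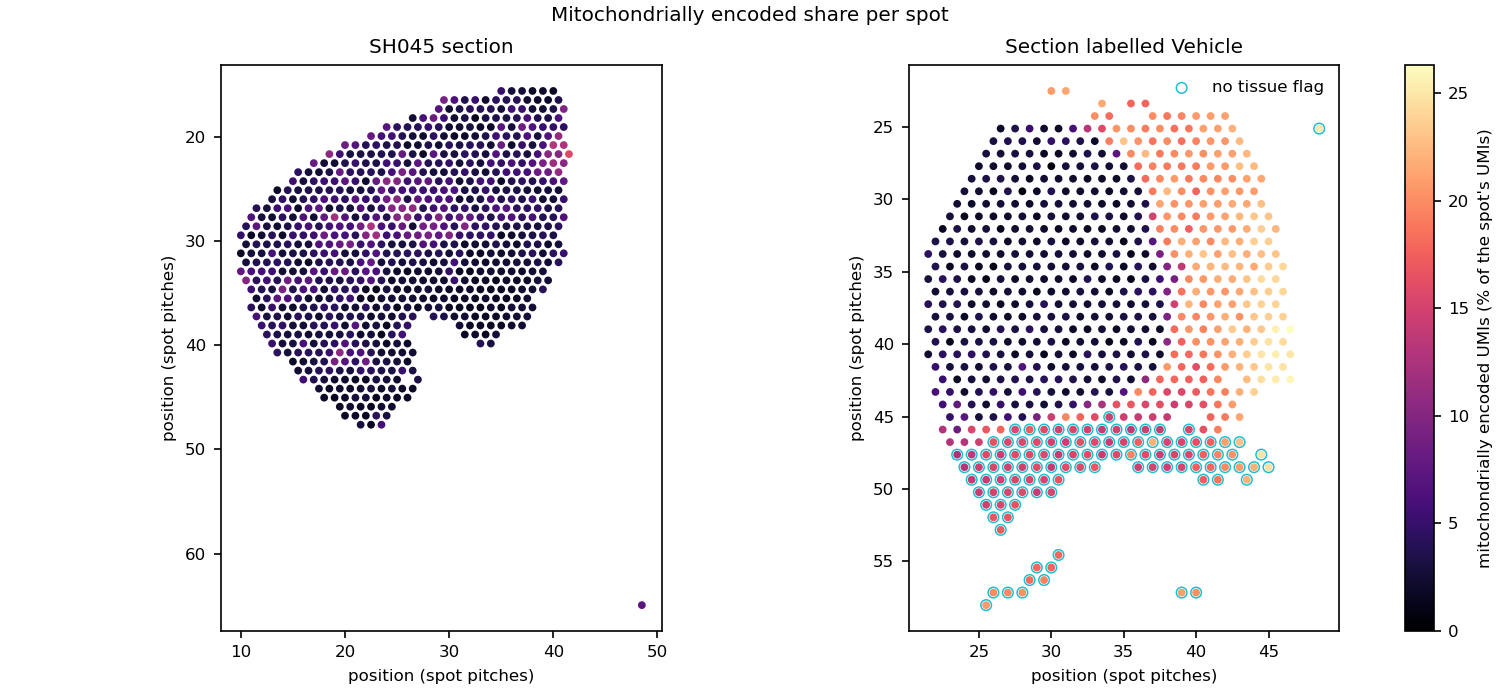
Share of mitochondrially encoded UMIs in each spot of the SH045 section (left) and the section labelled Vehicle (right) by colour, with axes in spot pitches; circles mark the 106 Vehicle spots without a tissue flag. The 342 Vehicle spots with at least 10% lie mostly on the right and lower sides of the section.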

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

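The tests of depth, region mix, an unobstructed kidney, Slc14a2 and nuclear mitochondrial genes were chosen after the results they concern had been seen, and the test of spread RNA before its result was seen.

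The positions table of the Vehicle section does not flag as tissue 106 spots that its matrix holds, a signal outside the outline that the table gives. These spots had a median of 7495 UMIs against 4473 UMIs in the 570 flagged spots, and all of them were among the 342 spots with at least 10% mitochondrially encoded counts. The table also flags 640 spots that the matrix does not hold.

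The mitochondria-rich Vehicle spots (342, with a median of 19.6% mitochondrially encoded counts against 2.74% in the other 334) lay mostly on the right and lower sides of the section. If transcripts had spread from the tissue into uncovered spots, neighbouring spots should share a smooth mixture. At equal UMIs, the median overdispersion of 29 tubule markers across spots was 4.90 times higher in the mitochondria-poor spots (2.31 to 9.64 by resampling genes). Overdispersion was higher there for 28 of the 29 markers. Spread RNA would give this, but it is not told apart from tissue make-up. Regions 2, 3 and 5, low in mitochondrially encoded counts, stood at 15402, 27740 and 4475 CPM of the first and second segment list. Regions 1 and 4, rich in these counts, stood closer together, at 20745.5 and 19341 CPM. Their median UMIs per spot were 3287 and 8716.5, against 4932.5 in the section. Tubules rich in mitochondria would raise the nuclear genes of oxidative phosphorylation too, and their median log2 ratio was -0.23 in the mitochondria-rich spots. CPM totals include mitochondrially encoded counts, at 188563 CPM in these spots and 31720 CPM in the others, which lowers every nuclear gene there. The value thus shows no clear rise rather than a fall, which argues against that source. Spread RNA and a tissue area of degraded RNA both stay open, and no biological explanation from the design was tested.

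Injury, matrix and immune genes stood far higher in the SH045 section than in the section labelled Vehicle, although the labels give ureteral obstruction for both. The injured tubule list was also higher over the 59 SH045 and 297 Vehicle spots with 5000 to 15000 UMIs. Its median log2 ratio there was 3.74 (3.60 to 4.22 by resampling spots). That interval takes spots as independent, which they are not, and leaves out the variation between mice and between sections. The comparison is a weak test of depth, since depth leaves the expected CPM as it is. The median spot in that range also still differed, at 12175 and 8143 UMIs. For a different mix of the regions seen here, only summed injured tubule genes were compared. Their level in the lowest SH045 region was 2.53-fold above that in the highest Vehicle region. Over 25 pairings of clustering settings the fold lay between 2.45 and 4.27. Spp1 alone gave 9151 of 14583 CPM in SH045 region 7 and 2607 of 5761 CPM in Vehicle region 5. The sum therefore does not decide this for the list as a whole. Matrix and immune lists were not put to this test. The lowest SH045 and highest Vehicle regions summed to 8572 and 3760 CPM for structural matrix and 3107 and 1046 CPM for macrophage markers. MHC class II gave 1962 and 859 CPM, MHC class I 2185 and 1288 CPM, and complement 1626 and 564 CPM. Chemokine and interferon sums were closer, at 1468 and 1031 CPM and at 764 and 635 CPM. The order was reversed for NF-kB genes (752 and 888 CPM), dendritic cell markers (30.5 and 38.5 CPM) and neutrophil markers (11.6 and 59.7 CPM). B and plasma cell sums were 282 and 248 CPM, and T and NK cell sums 24.2 and 23.8 CPM. An unobstructed kidney deposited as the Vehicle section stays open, as does an obstruction that failed: the 4.40 CPM of Havcr1 in the highest of 4 position blocks restates the pattern and decides neither. An effect of the treatment was not tested, since each group is 1 mouse, and neither was an exchange of the 2 section labels, because no transcript marks the compound.

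Slc14a2, a urea transporter gene of the inner medulla, was seen only in the SH045 section. It was 26.1-fold higher in its highest SH045 region than in its lowest. Even the lowest, at 11.9 CPM (7.88 to 17.1), was 13.9-fold above the 95% upper limit of 0.852 CPM over the whole Vehicle section. A different mix of these regions would not give this if each region kept its own RNA. Spread of Slc14a2 RNA from its high regions, such as 3 and 4 at 308 and 309 CPM, was not tested. Since spread could raise the low regions, the values do not decide on a different mix. Dio2 and Fst, which lead SH045 regions 3 and 4, also had no UMI in the Vehicle section.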

How the results depend on the processing

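The 3 choices of spots named here (low mitochondrial share, tissue flag, largest block) were added after seeing the data. None of 28 log2 ratios (TRPC genes with a UMI and the genes of highest or lowest ratio) changed sign: of 364 alternative values 224 stayed within the interval of the first value. Of 761 list medians 500 stayed within counting error and 254 moved, and 7 changed sign from a first value of at least 1.5-fold. Smaller first medians also crossed 0 under at least 1 alternative for thick ascending limb, podocyte, neutrophil, TRPC, glycolysis, hypoxia, iron and cell death and nuclear RNA lists. Of 84 correlations 57 stayed within the interval of the first value, and those that crossed 0 started below 0.1 (T and NK genes in the Vehicle section). The cause was not tested unless stated. Median log2 ratios under TMM and median-of-ratios factors were 3.29 and 3.25 for injured tubule, 3.18 and 3.15 for structural matrix, 2.49 and 2.45 for macrophage, and -2.43 and -2.47 for the first and second proximal segments. A pseudocount of 10 CPM gave 2.90, 2.86, 2.07 and -1.78 in the same order, and 0.1 CPM gave 4.28 for injured tubule and 4.18 for matrix. Genes with at least 50 CPM gave 3.52 and the mean over members 4.26 for injured tubule. Summed levels gave 2.61 for matrix and -2.05 for the proximal segments. Spots 3 or more steps from the edge gave 2.75 for macrophage and -1.91 for the proximal segments. For the latter, totals without mitochondrially encoded genes gave -1.94, also without ribosomal and haemoglobin genes -1.90, equal weight per spot -2.01, low mitochondrial share -1.92, the tissue flag -1.90 and the mean -1.93. Sign changes were found for the proximal straight segment (-0.019 with median-of-ratios factors, -0.93 at 50 CPM, -1.40 summed), for perirenal fat (-0.52 with TMM, -0.56 with median-of-ratios, -0.13 without mitochondrial, ribosomal and haemoglobin genes), where Car3, a gene outside the naming rule, reached 10 CPM and joined Fabp4. The value of 0.42 for mitochondrially encoded genes with Vehicle spots of low mitochondrial share follows from that choice of spots and tests nothing. The median of all genes was -0.017 with median-of-ratios factors when genes were chosen again after scaling. Resolution 0.3 gave 4 SH045 and 3 Vehicle regions, 1.0 gave 12 and 8, 1000 variable genes gave 10 and 4, and 10 principal components gave 10 and 5, with adjusted Rand indices against the first regions of 0.52 to 0.70 in both sections, so region borders depend on these settings. Thinning to the same median of UMIs per spot leaves the expected CPM as it is and is no test of depth. The correlation of matrix with macrophage genes was 0.33 in the SH045 and 0.41 in the Vehicle section on counts as deposited, and in the Vehicle section 0.21 by Spearman and 0.38 over spots of low mitochondrial share. The Havcr1 share of SH045 spots was 99.1% without thinning and 55.5% at 1250 UMIs. Clustering both sections together gave no value within shared regions, because none of the 6 joint clusters held spots of both. No paired analysis was possible because each section comes from a different mouse, with 1 per group. The 5.62-fold lower depth per spot limits what can be said of rare transcripts in the Vehicle section.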

Other observations

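The test of chemokine and matrix genes was set before its result was seen. Genes and regions in the first paragraphs are described as values, and Igha, Cck and Penk were picked after their values were seen.

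Immunoglobulin transcripts were unevenly spread in the SH045 section. Igha, the heavy chain gene of immunoglobulin A, stood at 3682 CPM in region 6 and at 282 CPM in region 3, against 1569 CPM over the whole section (1553 to 1586) and 147 CPM in the Vehicle section (135 to 158). Ighg2c had 871 UMIs in the SH045 section and none in the Vehicle section. The neuropeptide genes Cck and Penk stood at 54.4 and 38.5 CPM in the SH045 section and had 1 UMI each in the Vehicle section.

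The injury markers were not highest in the same places. Havcr1 peaked in region 2 at 1636 CPM and region 6 at 1556 CPM and was lowest in region 3 at 140 CPM, where Lcn2 was highest at 3576 CPM. Lcn2 was lowest in region 7, at 334 CPM. Mmp7 and Krt14 were highest in region 5, at 612 and 70.1 CPM. Of the 38 Trpc6 UMIs of the section, 14 lay in region 5, or 8.84 CPM (4.83 to 14.8), and none in regions 2 and 7.

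Chemokine genes led region 2 and structural matrix genes were highest in region 5, which raised the hypothesis that inflammatory tubules and matrix lie apart within regions 1 and 2. Such a separation was set to predict a correlation of -0.1 or lower between the chemokine and matrix scores across their 335 spots. The correlation was 0.27 (Spearman 0.22), and 0.15 over all 788 spots, so the hypothesis did not hold within regions 1 and 2 at the scale of a spot. That test left out region 5 and does not bear on differences between regions. Against the rest of the section, chemokine and matrix lists had median log2 ratios of 0.65 and -0.71 in region 2. In region 5 these were -0.48 and 1.31. By summed level, chemokine genes stood at 2178 CPM in region 2 against 1825 CPM in the rest. In region 5 they stood at 1983 CPM against 1913 CPM, so the lower chemokine median there was not seen in the sum.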
